A study of Mus musculus with 12 samples.

How the data were processed

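RNA was measured in 12 mouse tumours, 3 in each of 4 groups. The tumours grew from Lewis lung carcinoma (LLC) cells, a transplantable lung cancer line of C57BL/6 mice, put under the skin of the flank of female mice. Per the labels, the cells were given in Matrigel, 6 mice made up a group, and injections of 100 µL into the peritoneum started once a tumour reached 100 mm3 and went on 2 times per week for 4 weeks. The groups were vehicle, cisplatin (a platinum drug that cross-links DNA), brivanib (an inhibitor of VEGF and FGF receptor kinases) and the combination of both drugs. Doses are not given in the sources used here. The labels number the samples but do not say whether the 3 tumours of a group came from separate animals, so the p-values measure only the spread between these samples.

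The values are fragments per kilobase of transcript, scaled by a fragment total per library (FPKM). The authors estimated them for each transcript with RSEM after alignment with Bowtie2, per the labels' design text. The sequencer was a BGISEQ-500 per the same text. The submitters' processing notes also name HISAT and Bowtie, give version 2.2.5 for Bowtie2 and 1.2.12 for RSEM, and list the build mm9, whereas the design text names mm10. The coordinates in the deposited table settle the build of the annotation: of 135276 transcripts, 134952 were found in GENCODE release M21 on GRCm38 (mm10), and 98.48% of those found had identical coordinates there. All positions given here are those of the deposited table, on GRCm38. RNA was extracted with Trizol or an RNeasy kit per the labels' protocols, and no molecular identifiers or strand setting are named there. Of the per-sample columns, 1 matched no sample label and was not used in any step. A further 3 lines held broken annotation text and were dropped.

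In each library the FPKM value times the transcript length went in steps of 1 size, so fragments per gene were recovered from the deposited FPKM values. Of the values up to 100 fragments, 100% came out whole within 0.01 fragments in each library. The recovered depth was 17.161 M to 30.943 M (M, 1e6) fragments per library. Transcript FPKM values were summed to 53801 genes. Symbols came from a table of gene IDs that matched 53620 of them, and for 1618 of these the deposited table carried another name. A gene was tested where its mean FPKM over the 12 libraries was at least 1, which left 14246 genes. RSEM divides fragments between overlapping isoforms and near-identical copies, so values of the paired globin genes, of pseudogenes and of genes with several isoforms are uncertain in how they were split. Transfer RNA genes are shorter than a usual sequencing fragment, so their FPKM values are uncertain as levels.

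Group differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1). A mean per group was fitted to all 12 libraries, with 8 residual degrees of freedom, a mean-variance trend and moderated variances. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes; each is given ± its standard error (SE). FPKM levels are given as mean ± standard deviation (SD) with n = 3. The 5 pairwise contrasts were cisplatin, brivanib and the combination against vehicle, and the combination against each single drug. A contrast of contrasts, called the interaction, asked whether the effect of brivanib differed with and without cisplatin.

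Of 39 gene lists, 34 had at least 5 tested genes and were tested with camera from limma at a preset correlation of 0.01, adjusted over the 34 lists within a comparison. Camera asks whether a list ranks higher or lower than the other genes. Beside it stand camera with a correlation estimated from the 12 libraries and fry, which asks whether a list's genes move one way on balance. The count of changed genes in a list is given over all genes tested and adjusted over the list alone. The 5 lists not tested were regulatory T cell genes (4 of 11 members tested), B cell and plasma cell markers (1 of 19), lymphatic endothelial markers (2 of 10), skin keratinocyte markers (1 of 22) and Schwann cell and nerve markers (3 of 12). The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. By that rule the text names the 8 largest changes in each direction among genes past the threshold whose groups did not overlap, up to 4 members of each called list by the size of the moderated statistic, and a panel of 17 genes; where fewer than 3 genes passed in a direction, the 3 with the smallest p are given instead. Gene models with provisional names are counted but not named, and genes named outside the rule are marked as chosen after their values were seen.

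The procedure was tested on simulated data built on the real genes for cisplatin against vehicle, with 14092 genes. It called 3 of 66 genes changed 1.5-fold (4.5%), 37 of 67 changed 2-fold (55.2%) and 56 of 65 changed 4-fold (86.2%), with 0 in the wrong direction, and 6 of 13864 unchanged genes. A simulated list of 30 genes shifted 1.5-fold had an adjusted p = 2.91e-23 and adjusted p = 8.86e-05 with an estimated correlation, and 0 of 33 unchanged lists were called at the preset correlation. Each gene was simulated independently of the others. The list results of the simulation therefore do not test whether the preset correlation suits real lists, whose genes may vary together. With no effect simulated for the combination against brivanib, limma called 0 of 14092 genes.

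The alternatives were pseudocounts of 0.1 and 5, no filter, a mean FPKM of at least 5, rescaling each library to an equal total, median-of-ratios scaling, quantile normalization, fits on only the groups compared, robust variances, sample weights, the replicate number as a block, transcripts as features, an estimated correlation, and each of the 12 libraries left out in turn. Added after seeing the data were rescaling without ribosomal-like features, voom (limma) on the recovered fragments, and the skeletal muscle or adipocyte score of a library as a covariate. A fold against a group with 0 fragments in all 3 libraries is a lower bound, from a floor of 3 fragments per library. PCR copies were not removed by molecular identifiers, so floors cover counting error only. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for reading the table and for plots.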

Results

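Transcript levels were measured in LLC flank tumours of mice given vehicle, cisplatin, brivanib or both drugs, with 3 tumours per group. The series title presents brivanib, through the DNA sensor cGAS, as a sensitizer of tumours to chemotherapy that raises antitumour immunity. The comparisons ask what each drug and their combination did to the tumour transcriptome. Vehicle libraries 2, 3 and 5 held 21.822, 20.29 and 18.136 M recovered fragments (M, 1e6). Cisplatin libraries 1, 2 and 3 held 21.05, 22.683 and 20.579 M. Brivanib libraries 2, 3 and 5 held 21.623, 21.616 and 30.943 M. Combination libraries 2, 3 and 4 held 21.425, 22.809 and 17.161 M.

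Tumour pieces differed in their levels of muscle and fat marker genes. Skeletal muscle markers, such as the fast fibre genes Pvalb and Myl1, had a mean log2(FPKM + 1) of 0.437 to 0.46 in the vehicle libraries. They were at 4.141 in brivanib 3, 3.836 in brivanib 5, 2.279 in combination 2, 1.543 in cisplatin 1 and 1.318 in cisplatin 3. Adipocyte markers averaged 1.545 to 1.609 in vehicle, 1.667 and 1.823 in cisplatin 2 and 3 but 2.971 in cisplatin 1, and 3.22 to 3.579 in the combination libraries. In brivanib 2, 3 and 5 they were at 2.195, 4.34 and 2.376. In brivanib 5, ribosomal-like features took 37.819% of the recovered fragments, against 0.237% to 0.611% in the other 11 libraries. These features are annotated ribosomal RNA genes and gene models with ribosomal RNA sequence. The FPKM total was 921510.4 in brivanib 5, against 471827.7 (vehicle 3) to 527656.7 (brivanib 2) in the others. Without ribosomal-like features brivanib 5 held 19.241 M fragments. The step of its FPKM values corresponds to a scaling total of 21.021 M fragments, below the 30.943 M recovered. The deposited scale of this library thus did not count all recovered fragments. Rescaling to equal totals does count them, which lowers the other genes of brivanib 5. After rescaling every library to the same total, the median log2 fold change of all genes was -0.36 for brivanib against vehicle, 0.32 for the combination against brivanib and 0.32 for the interaction. On the deposited scale these medians were -0.01, 0.04 and -0.02.

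**Figure D1:**
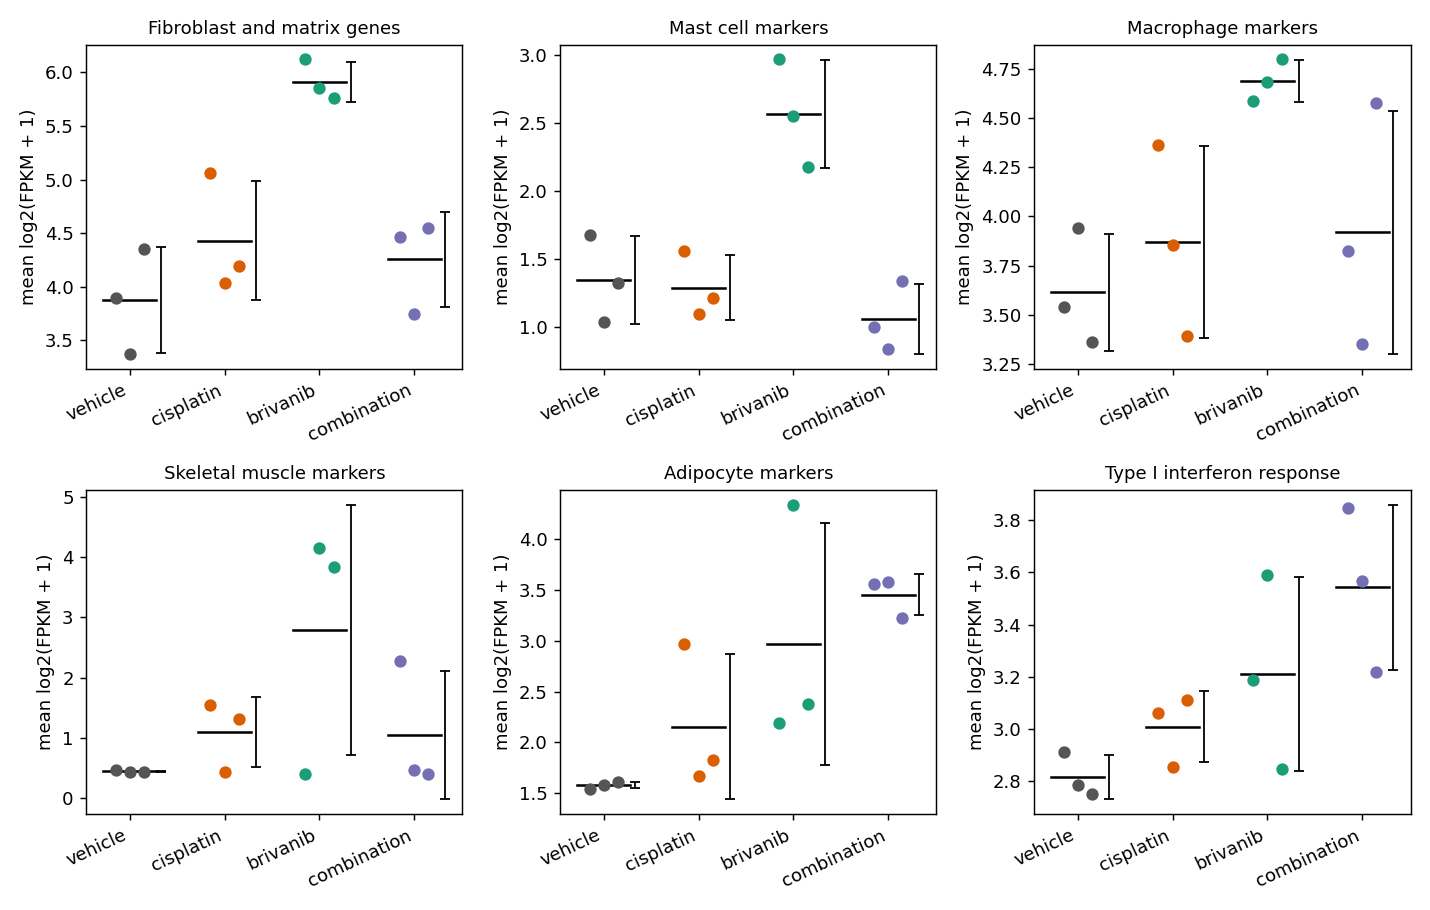
Mean log2(FPKM + 1) of 6 gene lists in each of the 12 libraries (points), with the group mean (horizontal line) and its SD (bar at the right, n = 3); most axes do not start at 0. Fibroblast and matrix genes lie at 5.757 to 6.12 in the brivanib libraries and at 3.374 to 5.06 in all others, and skeletal muscle markers are high in brivanib 3 and 5 but not in brivanib 2, at 0.405.

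Cisplatin alone was compared with vehicle. The most marked difference was a loss of red cell transcripts. Hbb-bs, an adult beta globin gene (chromosome 7, 103826534 to 103828096), fell from 1025 ± 322 to 13.1 ± 17.4 FPKM (SD, n = 3), a log2 fold change of -7.29 ± 1.01 (adjusted p = 0.0268). Hba-a2, Hbb-bt and Hba-a1 fell by 6.61, 6.52 and 5.71 on the log2 scale. Alas2, the erythroid enzyme that starts haem synthesis (chromosome X, 150547375 to 150570638), fell from 14.2 ± 3.53 to 0.633 ± 0.745 FPKM (-3.28 ± 0.42, adjusted p = 0.0225). Wee1, a kinase that holds back entry into mitosis (chromosome 7, 110122046 to 110143286), rose from 13.7 ± 0.504 to 28.3 ± 6.96 FPKM (0.97 ± 0.15, adjusted p = 0.0385). Lrrc8d, a subunit of the volume-regulated anion channel that can carry cisplatin into cells, also rose (1.98 ± 0.33, adjusted p = 0.0459).

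In all, 27 of 14246 genes changed with cisplatin, 17 up and 10 down, and 11 of them by at least 2-fold. Other increases were in Zbtb6, a zinc finger factor (2.10 ± 0.28), the mitochondrial leucine transfer RNA mt-Tl1 (1.98 ± 0.26), the acyl-CoA synthetase Acsbg1 (1.54 ± 0.24) and the complex I subunit mt-Nd5 (1.10 ± 0.19). The zinc transporter Slc39a9 (0.99 ± 0.17) and the prostaglandin synthase Ptgs1 (0.95 ± 0.15) rose too, all with adjusted p from 0.0225 to 0.049. Spaca6, a sperm-egg fusion protein, the synaptic scaffold Dlg4 and the sugar transferase Ogt fell by 0.85, 0.60 and 0.57 on the log2 scale. Of 28 alternatives mt-Nd5 lost its call in 22, Lrrc8d and Slc39a9 in 21, Wee1, Ogt and Spaca6 in 19, Acsbg1 in 18, Hba-a2 in 16 and Ptgs1 in 15. The share of higher calls differed with scaling, while the named genes kept the sign of their fold change. On the deposited scale 63% were higher, against 28.6% of 14 under median-of-ratios scaling, 18.8% of 16 under quantile normalization, 46.2% of 13 after rescaling to equal totals and 36.4% of 11 with ribosomal-like features removed. limma called 0 genes without vehicle 2, 3 or 5 (1641, 1438 and 1914 at an unadjusted p under 0.05), and voom called 0 (1855 unadjusted). Without cisplatin 1 or 3 limma called 5 and 3, all lower. The count was 9 without brivanib 5, 10 without combination 2, 100 without brivanib 2 and 42 without brivanib 3.

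For cisplatin camera called 10 lists, 4 higher and 6 lower, at the preset correlation and 0 with an estimated correlation, and fry called 4. Erythroid markers were lower. Of this list 5 of 5 tested genes fell over all genes and 5 adjusted over the list alone, with a median of -6.52 (adjusted p = 1.84e-15, adjusted p = 0.137 with an estimated correlation). Proliferation genes stood higher, with a median of 0.46 over 40 genes (adjusted p = 6.15e-21, adjusted p = 0.421 with an estimated correlation). Over all genes 0 passed, while 34 rose adjusted over the list alone. Among them the mitotic cyclin Ccnb2 had 0.77 ± 0.14, the anaphase activator Cdc20 0.72 ± 0.13 and the spindle factor Tpx2 0.62 ± 0.13, at adjusted p of 0.0598, 0.0598 and 0.0754. Of 13 mitochondrially encoded genes 1 rose, mt-Nd5, and 4 adjusted over the list alone, with a median of 0.40 (adjusted p = 0.000111, adjusted p = 0.594 with an estimated correlation). DNA repair genes had a median of 0.17, with 0 of 40 past the test and 4 adjusted over the list alone (adjusted p = 0.0161, adjusted p = 0.594 with an estimated correlation). Its strongest members were Brca1 (0.54 ± 0.13, adjusted p = 0.102) and the mismatch repair gene Msh6 (0.60 ± 0.15, adjusted p = 0.111). Interferon-gamma response genes had a median of 0.30, with 0 of 27 changed over all genes and 0 adjusted over the list alone (adjusted p = 0.0405, adjusted p = 0.893 with an estimated correlation).

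Vascular and hypoxia lists stood lower in cisplatin tumours. The 32 hypoxia response genes had a median of -0.29 (adjusted p = 5.09e-06, adjusted p = 0.814 with an estimated correlation). The 22 VEGF and tip cell genes, which include the placental growth factor Pgf (-1.43 ± 0.60, adjusted p = 0.296), had a median of -0.25 (adjusted p = 0.000542, adjusted p = 0.489 with an estimated correlation). Pericyte and smooth muscle markers had a median of -0.45 (adjusted p = 0.000551, adjusted p = 0.421 with an estimated correlation). The pericyte gene Rgs5 was at -1.0 ± 0.21 (adjusted p = 0.0773). T cell markers had a median of -0.21 (adjusted p = 0.0208, adjusted p = 0.489 with an estimated correlation), and the receptor chain Cd3g was at -1.48 ± 0.43 (adjusted p = 0.151). Endothelial markers had a median of -0.15 (adjusted p = 0.0405, adjusted p = 0.893 with an estimated correlation). Its members Eng and Plvap were at 0.50 ± 0.15 and 0.71 ± 0.23, and the list's median was 0.06 without cisplatin 1. Over all genes 0 members of these 5 lists passed limma's test. Adjusted over the list alone, 1 pericyte gene and 1 T cell gene fell. Without cisplatin 1, the T cell, endothelial and DNA repair calls were lost. The endothelial call was also lost without vehicle 3 or 5 or brivanib 2 or 3. Both tissue scores as covariates ended the T cell, endothelial, DNA repair and interferon-gamma calls. DNA repair was lost without vehicle 2, and interferon-gamma without vehicle 5, cisplatin 2, brivanib 2 or combination 3.

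**Figure D2:**
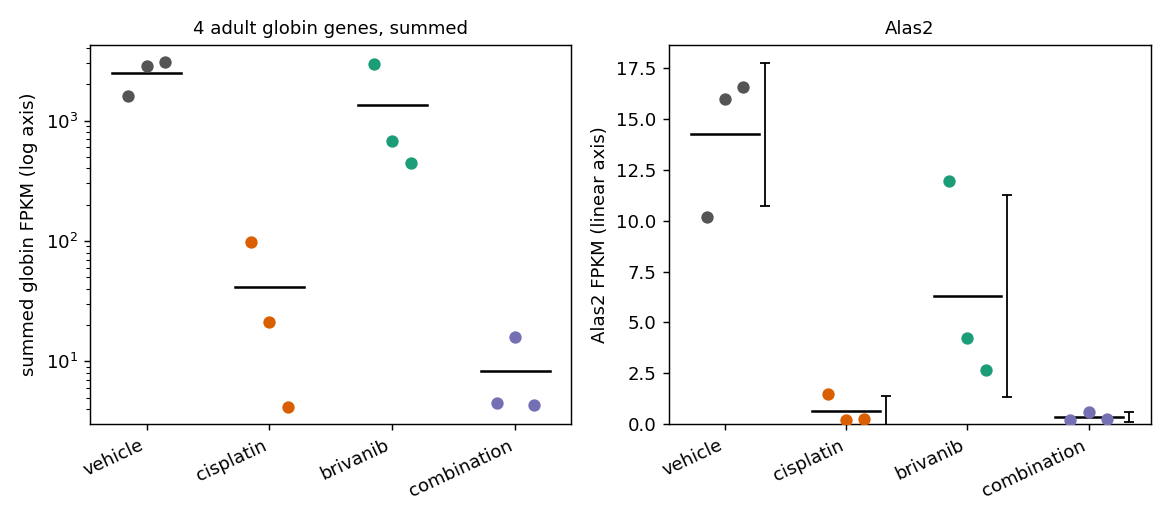
Summed FPKM of the 4 adult globin genes (left, logarithmic axis) and FPKM of Alas2 (right, linear axis) in each library (points), with arithmetic group means as horizontal lines and, at the right only, SD bars (n = 3, drawn down to 0). Summed globin FPKM lay at 1597 to 3069 in vehicle, 446.1 to 2927 in brivanib, 4.199 to 98.11 in cisplatin and 4.324 to 15.86 in combination libraries.

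With brivanib alone, connective tissue and acute phase genes were higher than with vehicle. Col1a1, which encodes the main fibrillar collagen chain (chromosome 11, 94936224 to 94953042), rose from 13.8 ± 14.5 to 314 ± 145 FPKM (SD, n = 3), a log2 fold change of 4.85 ± 0.84 (adjusted p = 0.0118). Saa3, an acute phase serum amyloid (chromosome 7, 46711998 to 46715700), rose from 0.337 ± 0.353 to 103 ± 68.8 FPKM (5.98 ± 0.84, adjusted p = 0.00402). The chemokine Cxcl14 (4.66 ± 0.61), collagen Col1a2 (4.61 ± 0.80) and the collagen cross-linking enzyme Lox (4.57 ± 0.76) also rose. So did chemerin Rarres2 (4.32 ± 0.71), haptoglobin Hp (4.30 ± 0.83) and the protease inhibitor Serpina3n (4.30 ± 0.56), with adjusted p from 0.00348 to 0.0204.

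A total of 258 genes changed with brivanib, 243 up and 15 down, 206 of them by at least 2-fold. Decreases were smaller. The cyclin pseudogene Ccnb2-ps fell by 1.19, the cell survival gene Bcl2l2 by 0.86, the nuclear exporter Xpo7 by 0.83, and Chic1 by 0.78 on the log2 scale. The transcription co-regulator Cited2 fell by 0.66, the membrane protease Rhbdl2 by 0.63, and the tetraspanin Cd82 and the cholesterol ester hydrolase Nceh1 by 0.52 each on the log2 scale. Xpo7 had 3808 to 4092 fragments per vehicle library and 3678 to 4289 per brivanib library. Its fragments thus overlapped between the groups, while its FPKM, which depends on how fragments are split between isoforms, did not. With transcripts as features, the most abundant transcripts of Xpo7 and Cd82 had log2 fold changes of 0.71 and 0.09. The count was 124, 116 and 159 without vehicle 2, 3 and 5, 154 without brivanib 5, 62 with the muscle score as a covariate and 24 with the adipocyte score as a covariate.

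For brivanib camera called 16 lists and fry called 5. Fibroblast and matrix genes stood out among the 16 that camera called. Over all genes 18 of 30 rose, and 20 rose adjusted over the list alone, with a median of 2.24 (adjusted p = 3.03e-24, adjusted p = 0.124 with an estimated correlation). Among them were the fibroblast gene Pi16 (3.33 ± 0.29, adjusted p = 0.000465), Fbln1 (2.84 ± 0.32), Loxl1 (3.22 ± 0.39) and fibrillin Fbn1 (2.95 ± 0.41). Pericyte and smooth muscle markers had a median of 0.22 (adjusted p = 0.00343, adjusted p = 0.32 with an estimated correlation). Over all genes 2 of 13 rose, Tagln (2.55 ± 0.36) and smooth muscle actin Acta2 (2.38 ± 0.42), and 4 adjusted over the list alone. Skeletal muscle markers had a median of 2.39 with 0 of 16 past the test over all genes and 13 adjusted over the list alone (adjusted p = 1.07e-09, adjusted p = 0.357 with an estimated correlation). Pvalb and Myl1, at 0 fragments in all vehicle libraries, were at least 48-fold and 136-fold higher on average in brivanib without passing the test (adjusted p = 0.179 and 0.189). Adipocyte markers had a median of 1.23, or 1.13 with genes at 0 set to their floor (adjusted p = 1.1e-05, adjusted p = 0.357 with an estimated correlation). Of 12 such genes 0 passed over all genes and 3 adjusted over the list alone, and the call ended with the muscle score as a covariate.

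Myeloid and mast cell genes were higher in brivanib tumours as well. The 21 macrophage markers had a median of 1.21 (adjusted p = 2.25e-10, adjusted p = 0.226 with an estimated correlation). The scavenger receptor Cd163 (2.87 ± 0.44, adjusted p = 0.00652) and Cd68 (1.30 ± 0.27) rose, and 14 rose adjusted over the list alone. The call of Cd68 was lost in 17 of 28 alternatives. The 20 chemokines had a median of 1.27 (adjusted p = 3.23e-09, adjusted p = 0.124 with an estimated correlation). Of these 6 rose, among them Cxcl14, Ccl6 (1.82 ± 0.28), the eosinophil attractant Ccl11 (2.17 ± 0.35) and Ccl9 (1.44 ± 0.27), and 8 adjusted over the list alone. Mast cell proteases Tpsb2 (1.81 ± 0.32), Cpa3 (1.72 ± 0.34), Cma1 (2.07 ± 0.44) and Mcpt4 (1.91 ± 0.43) rose, but of 27 alternatives Mcpt4 lost its call in 23, Cpa3 in 14 and Cma1 in 12. The proteases were 4 of 6 markers over all genes and 4 adjusted over the list alone, with a median of 1.77 (adjusted p = 0.000127, adjusted p = 0.124 with an estimated correlation). MHC class II genes had a median of 1.09 (adjusted p = 4.42e-08, adjusted p = 0.157 with an estimated correlation). H2-DMa, which loads peptides, rose (1.09 ± 0.22), 1 of 11, and 8 adjusted over the list alone. The immunosuppressive myeloid list had a median of 0.96 (adjusted p = 3.08e-06, adjusted p = 0.218 with an estimated correlation). In it the interleukin-4 receptor Il4ra rose (1.38 ± 0.23), 1 of 15, and 3 adjusted over the list alone. The neutrophil list had a median of 1.21 (adjusted p = 1.36e-05, adjusted p = 0.47 with an estimated correlation), 0 of 13 changed and 1 adjusted over the list alone. Dendritic cell markers had a median of 0.22 (adjusted p = 0.0042, adjusted p = 0.124 with an estimated correlation), with Clec10a up (2.04 ± 0.38), 1 of 14, and 2 adjusted over the list alone. The dendritic call ended with the muscle or the adipocyte score as a covariate and at a mean FPKM of at least 5.

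Type I interferon response genes had a median of 0.40 with brivanib (adjusted p = 7.03e-07, adjusted p = 0.47 with an estimated correlation). Here 2 of 37 rose, Ifi27l2a (2.02 ± 0.23, adjusted p = 0.00174) and Epsti1 (0.73 ± 0.15), and 4 adjusted over the list alone. The list call was lost with the muscle or the adipocyte score as a covariate, where the lowest median was -0.04, and Epsti1 lost its call in 16 of 27 alternatives and the hypoxia gene P4ha2 in 17 of 28. The proliferation median was 0.23 with 0 of 40 past the test over all genes and 0 adjusted over the list alone (adjusted p = 8.39e-08, adjusted p = 0.47 with an estimated correlation). Hypoxia response genes had a median of 0.27, with the collagen hydroxylase P4ha2 up (1.49 ± 0.33), 1 of 32, and 2 adjusted over the list alone (adjusted p = 0.00149, adjusted p = 0.729 with an estimated correlation). The median was -0.04 without brivanib 2, and the call was also lost without vehicle 2. Cytotoxic and NK cell genes stood lower at -0.22, with 0 of 23 past the test and 1 lower adjusted over the list alone (adjusted p = 0.0042, adjusted p = 0.47 with an estimated correlation), a call lost without brivanib 3. With either tissue score as a covariate the direction of the cytotoxic list turned, to a median of at most 0.26, and the call ended. Either score ended the proliferation call, and with the muscle score camera's direction for that list turned. Erythroid markers had a median of -1.27 with 0 of 5 past the test over all genes and 0 adjusted over the list alone (adjusted p = 0.00909, adjusted p = 0.47 with an estimated correlation), lost without brivanib 3 or 5 or with the muscle score as a covariate.

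In the combination against vehicle, red cell transcripts were lower, as with cisplatin, and some interferon and cell cycle genes were higher. Hbb-bs had 0 fragments in all 3 combination libraries and was at least 4440-fold lower than in vehicle. Hbb-bt, also at 0, was at least 1620-fold lower. Hba-a2, Hba-a1 and Alas2 fell by 8.44, 6.12 and 3.5 on the log2 scale, at adjusted p of 0.00463 each. Chil3, a chitinase-like protein of myeloid cells (chromosome 3, 106147554 to 106167564), rose from 0.84 ± 0.363 to 26.1 ± 22.6 FPKM (SD, n = 3), or 3.59 ± 0.46 (adjusted p = 0.00674). Tsc22d3, a gene induced by glucocorticoids (chromosome X, 140539528 to 140600659), rose from 19.4 ± 4.31 to 122 ± 82.2 FPKM (2.42 ± 0.46, adjusted p = 0.0235).

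With both drugs 333 genes changed against vehicle, 259 up and 74 down, 116 by at least 2-fold. Hp (4.26 ± 0.83), Serpina3n (3.66 ± 0.56), the epithelial keratin Krt20 (3.02 ± 0.70), Zbtb6 (2.30 ± 0.28) and Acsbg1 (2.28 ± 0.24) rose. So did resistin Retn (2.03 ± 0.45, adjusted p = 0.0397), which had 0 fragments in vehicle and was at least 20.4-fold higher. Prnd, a relative of the prion gene, the imprinted gene Mest and the cornified envelope gene Sprr1a fell by 2.30, 2.16 and 1.89 on the log2 scale. The calls of Krt20, Retn and the MHC class I gene H2-T22 were lost in 20 of 28, 14 of 27 and 19 of 28 alternatives. The share of higher calls was 77.8% on the deposited scale. It was 65.7% of 315 under median-of-ratios scaling, 61.9% of 299 under quantile normalization, 60.6% of 226 with ribosomal-like features removed and 60.2% of 266 with voom. The count was 41, 21 and 99 without vehicle 2, 3 and 5, 46 without combination 2, 50 without combination 3 and 525 without brivanib 2. Other settings gave 125 with no filter and 85 after rescaling to equal totals. With the adipocyte score as a covariate, which was higher in every combination than in every vehicle library, limma called 0 (1462 at an unadjusted p under 0.05).

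For the combination against vehicle camera called 14 lists and fry called 9. Of the 14 that camera called, proliferation and type I interferon were the most populated. Over all genes 11 of 40 proliferation genes rose and 29 adjusted over the list alone, with a median of 0.47 (adjusted p = 4.71e-16, adjusted p = 0.446 with an estimated correlation). They include the mitotic ubiquitin enzyme Ube2c (0.85 ± 0.13), the replication factor Cdc45 (0.63 ± 0.11), Tpx2 (0.70 ± 0.13) and the kinesin Kif20a (0.96 ± 0.18). Of 37 type I interferon genes 6 rose and 23 adjusted over the list alone, with a median of 0.72 (adjusted p = 1.49e-13, adjusted p = 0.446 with an estimated correlation). Those past the test include Oas1a, which senses double-stranded RNA (1.28 ± 0.22, adjusted p = 0.0207), Xaf1 (1.34 ± 0.26), Ifit2 (0.71 ± 0.14) and Ifi27l2a (1.15 ± 0.23). Interferon-gamma genes had a median of 0.51 with 0 of 27 past the test over all genes and 4 adjusted over the list alone (adjusted p = 0.000622, adjusted p = 0.551 with an estimated correlation), lost without vehicle 5. MHC class I genes had a median of 0.24 with H2-T22 up (0.50 ± 0.11), 1 of 22, and 7 adjusted over the list alone (adjusted p = 0.00919, adjusted p = 0.551 with an estimated correlation), also lost without vehicle 5. Mitochondrially encoded genes had a median of 0.50 (adjusted p = 1.5e-06, adjusted p = 0.446 with an estimated correlation). The complex I genes mt-Nd5, mt-Nd1 and mt-Nd6 rose by 1.14 ± 0.19, 1.21 ± 0.22 and 1.17 ± 0.23, 3 of 13, and 7 adjusted over the list alone.

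Vascular markers were lower with both drugs. Endothelial markers had a median of -0.48 (adjusted p = 4.85e-08, adjusted p = 0.446 with an estimated correlation). Ecscr (-0.72 ± 0.12, adjusted p = 0.0188) and Cd93 (-1.01 ± 0.22) fell, 2 of 27, and 5 adjusted over the list alone. VEGF and tip cell genes had a median of -0.39, with 0 of 22 past the test over all genes and 5 lower adjusted over the list alone (adjusted p = 1.5e-06, adjusted p = 0.446 with an estimated correlation). Pericyte and smooth muscle markers had a median of -0.38 (adjusted p = 0.00937, adjusted p = 0.446 with an estimated correlation). Rgs5 (-1.41 ± 0.21, adjusted p = 0.0102) and Mcam (-0.93 ± 0.21) fell, 2 of 13, and 3 fell and 1 rose adjusted over the list alone. Erythroid markers fell in 5 of 5 genes over all genes and 5 adjusted over the list alone, with a median of -8.33, or -8.06 with genes at 0 set to their floor (adjusted p = 1.49e-13, adjusted p = 0.198 with an estimated correlation).

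Adipocyte markers were higher with both drugs, with a median of 1.84, or 1.78 with genes at 0 set to their floor (adjusted p = 1.49e-06, adjusted p = 0.446 with an estimated correlation). The fatty acid carrier Cd36 (1.93 ± 0.35) and Retn rose, 2 of 12, and 9 adjusted over the list alone. Neutrophil markers had a median of 0.84 with 0 of 13 past the test and 1 adjusted over the list alone (adjusted p = 0.0216, adjusted p = 0.725 with an estimated correlation), lost without vehicle 2 or combination 3. p53 targets had a median of 0.21 with the drug pump Abcb1b up (0.67 ± 0.13), 1 of 30, and 6 adjusted over the list alone (adjusted p = 0.0247, adjusted p = 0.446 with an estimated correlation), lost without vehicle 5 or combination 3. Genes of the unfolded protein and integrated stress response had a median of 0.22 with 0 of 22 past the test over all genes and 0 adjusted over the list alone (adjusted p = 0.0384, adjusted p = 0.725 with an estimated correlation), lost without vehicle 2 or 5 or combination 2 or 3. The hypoxia median was -0.24 (adjusted p = 0.0324, adjusted p = 0.779 with an estimated correlation), although Angptl4, which blocks lipoprotein lipase, rose (1.92 ± 0.41, adjusted p = 0.0343), 1 of 32 and 1 adjusted over the list alone. Without vehicle 3 or 5 or combination 3 or 4 the hypoxia call was lost, and the median was 0.35 with the adipocyte score as a covariate.

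**Figure D3:**
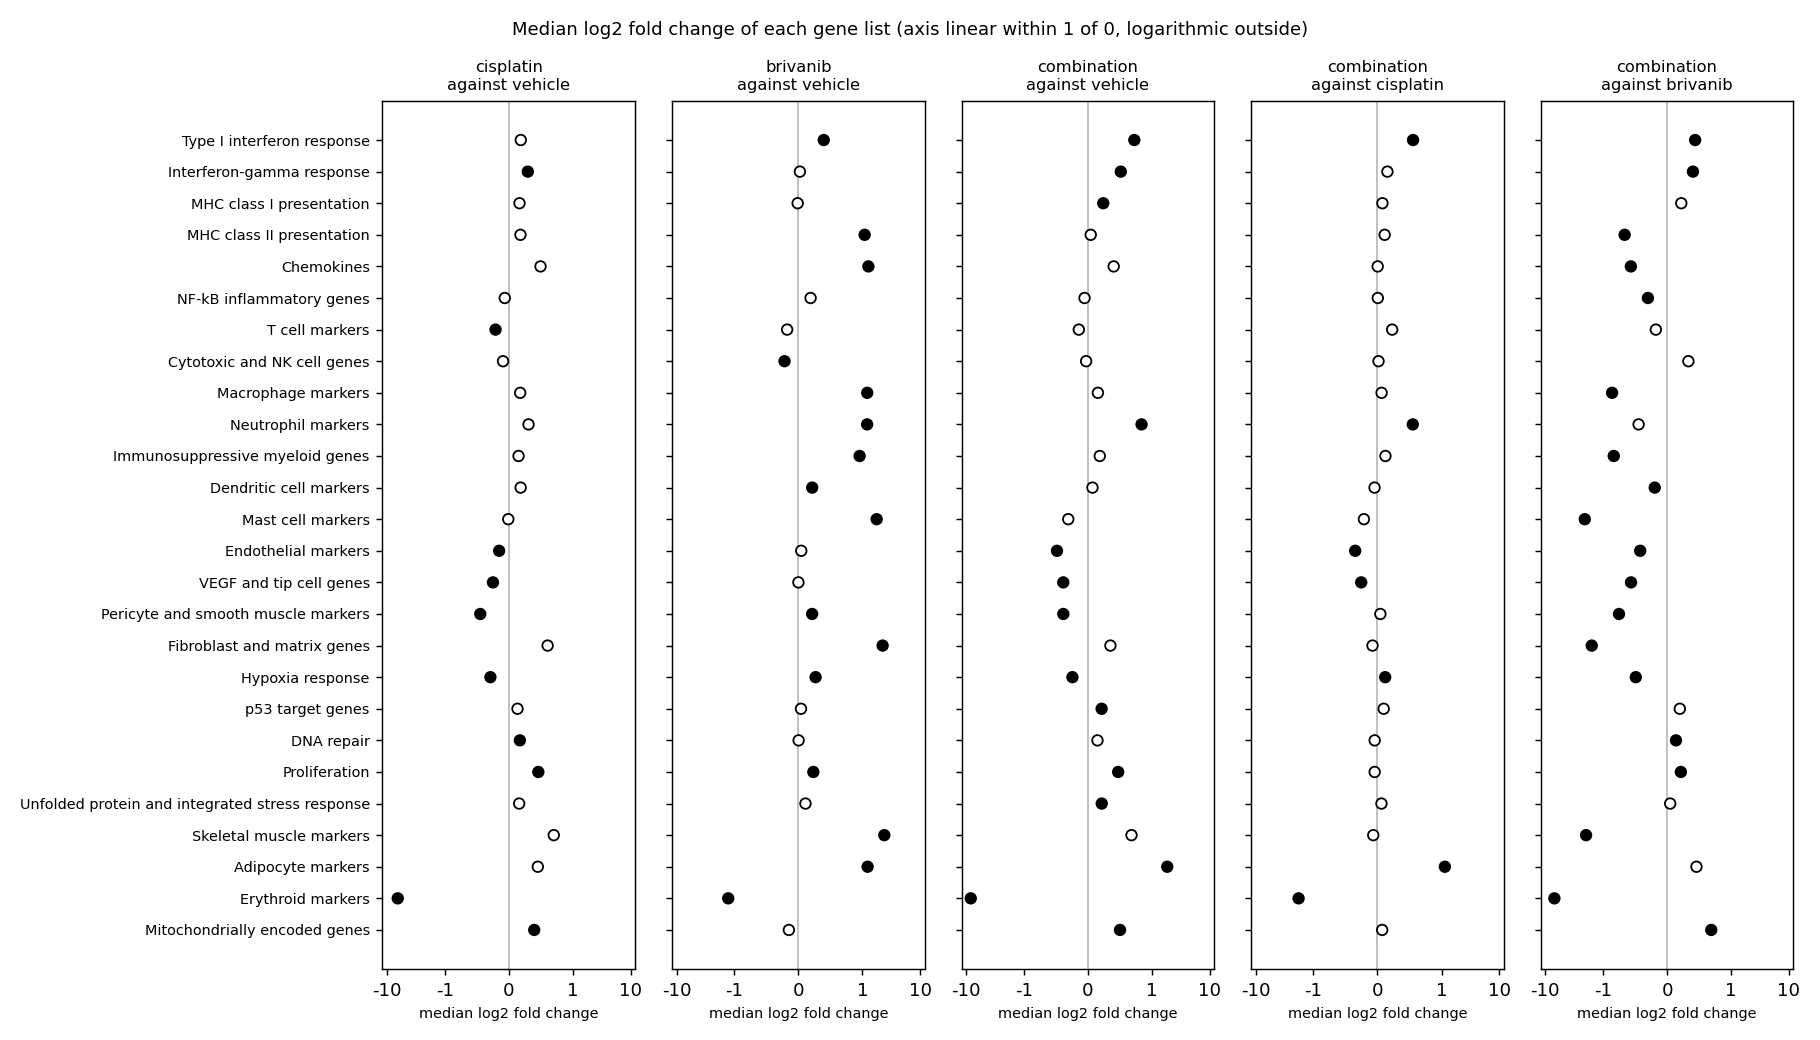
Median log2 fold change of the gene lists called in at least 1 of the 5 pairwise comparisons (filled points, called by camera at the preset correlation; open points, not called); the horizontal axis is linear within 1 of 0 and logarithmic outside. Erythroid markers lie lowest, at -6.52 for cisplatin and -8.33 for the combination against vehicle, and matrix genes at 2.24 for brivanib against vehicle and -1.57 for the combination against brivanib.

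Adding brivanib to cisplatin, in the combination against cisplatin alone, moved no single gene past the threshold. limma called 0 genes, with 960 at an unadjusted p under 0.05 and a smallest adjusted p of 0.588, and voom also called 0 (955 unadjusted). The smallest p-values belonged to the developmental gene Hoxc6 (0.87 ± 0.16), Ccdc77 (0.62 ± 0.12) and Nbdy (0.46 ± 0.10) on the higher side. On the lower side they belonged to Mest (-1.79 ± 0.31), the amino acid enzyme Gstz1 (-0.72 ± 0.12) and Prnd (-2.12 ± 0.41), and all had adjusted p from 0.588 to 0.619. The count was 2 without cisplatin 1, 1 without cisplatin 3 and 2 without combination 3, 3 with no filter, 1 after rescaling to equal totals and 15 with transcripts as features.

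In this comparison camera called 7 lists at the preset correlation and 0 with an estimated correlation, and fry called 0. Type I interferon genes were higher in the combination than in cisplatin tumours as a list by camera, with a median of 0.56 over 37 genes (adjusted p = 9.04e-21, adjusted p = 0.934 with an estimated correlation). Over all genes 0 passed, and 6 rose adjusted over the list alone. The antiviral genes Oas2 and Oas3 were at 1.0 ± 0.29 and 0.92 ± 0.27 and the interferon-induced protease Usp18 at 1.05 ± 0.31, each at an adjusted p of 0.657. Adipocyte markers had a median of 1.14, with 0 of 12 changed and 3 adjusted over the list alone (adjusted p = 1.54e-07, adjusted p = 0.934 with an estimated correlation). The fatty acid binding gene Fabp4 was at 3.21 ± 0.79 (adjusted p = 0.657). Endothelial markers had a median of -0.35, with 0 of 27 changed and 1 lower adjusted over the list alone (adjusted p = 3.05e-07, adjusted p = 0.985 with an estimated correlation). Ecscr was at -0.60 ± 0.12 (adjusted p = 0.619). Neutrophil, hypoxia, VEGF and tip cell, and erythroid lists were called with medians of 0.55, 0.12, -0.25 and -1.81, the last being -1.54 with genes at 0 set to their floor (adjusted p = 0.0275, 0.0275, 0.0363 and 0.0363, and adjusted p = 0.985 with an estimated correlation for each). Over all genes and adjusted over the list alone 0 of their 13, 32, 22 and 5 genes passed. These 4 calls were lost without single libraries. This held for neutrophil without cisplatin 1 or 3 or combination 3 and for hypoxia without cisplatin 3 or combination 2. It also held for VEGF and tip cell without cisplatin 2, brivanib 3 or combination 3 or 4, and erythroid without cisplatin 1, brivanib 3 or combination 2 or 4.

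In the combination against brivanib alone, matrix, mast cell and globin transcripts were lower. Skeletal muscle scores differed too, at 0.405, 4.141 and 3.836 in brivanib 2, 3 and 5 and 0.4 to 2.279 in the combination. Camera's matrix and mast cell calls were kept in 27 of 27 and 26 of 26 alternatives. This score and the adipocyte score as covariates were among them. Carried-along tissue other than muscle and fat was not tested. Cd209f, a C-type lectin (chromosome 8, 4102787 to 4105835), fell from 16 ± 2.52 to 0.333 ± 0.314 FPKM (SD, n = 3), a log2 fold change of -3.69 ± 0.22 (adjusted p = 1.84e-05), and stood at 0.0924 ± 0.16 FPKM in vehicle. Hbb-bs and Hbb-bt, at 0 fragments in the combination, were at least 2380-fold and 901-fold lower. Hba-a2, Hba-a1, Saa3, Col1a1 and the pseudogene Mid1-ps1 fell by 7.17, 4.85, 3.91, 3.32 and 3.29 on the log2 scale, with adjusted p from 0.00654 to 0.0497. Col1a1 lost its call in 22 of 28 alternatives, Mid1-ps1 in 16 of 27 and Saa3 in 11 of 28, and Hba-a1 in 0 of 28. Chil3 (2.89 ± 0.46), Tsc22d3 (2.49 ± 0.46), the interferon-inducible Ifi207 (2.46 ± 0.22, adjusted p = 0.000671), the inflammasome sensor Naip1 (1.98 ± 0.27) and the clock gene Per1 (1.84 ± 0.28) rose. So did the mitochondrial transfer RNAs mt-Ta (2.19 ± 0.45), mt-Tw (2.07 ± 0.33) and mt-Tn (1.92 ± 0.35).

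Between the combination and brivanib 551 genes changed, 288 up and 263 down, 248 by at least 2-fold. The share of higher calls was 52.3%, but 69.1% of 317 at a mean FPKM of at least 5 and 27.5% of 138 in a fit of these groups alone. It was 38.3% of 214 without brivanib 5, 44.1% of 170 without combination 2 and 32.8% of 61 without combination 3. Rescaling to equal totals gave 269 genes and sample weights gave 1077. Of 30 matrix genes 15 fell over all genes and 25 adjusted over the list alone, with a median of -1.57 (adjusted p = 4.21e-22, adjusted p = 0.12 with an estimated correlation). Examples are Pi16 (-3.02 ± 0.29), Fbln1 (-2.45 ± 0.32), Sparc (-1.79 ± 0.24) and Col6a3 (-2.06 ± 0.31). Of 13 pericyte and smooth muscle markers 6 fell and 8 adjusted over the list alone, with a median of -0.75 (adjusted p = 3.74e-07, adjusted p = 0.12 with an estimated correlation). Among those that fell were Rgs5 (-1.47 ± 0.21), Acta2 (-2.44 ± 0.42) and Tagln (-2.03 ± 0.36). Endothelial markers had a median of -0.42 (adjusted p = 3.74e-07, adjusted p = 0.45 with an estimated correlation). Ecscr (-0.97 ± 0.12), Cd34 (-1.55 ± 0.25), Cd93 (-1.05 ± 0.22) and the angiopoietin receptor Tek (-0.88 ± 0.21) fell, 4 of 27, and 7 adjusted over the list alone. VEGF and tip cell genes had a median of -0.56 (adjusted p = 8.09e-06, adjusted p = 0.24 with an estimated correlation). The basement membrane laminin Lama4 (-1.62 ± 0.21) and the netrin receptor Unc5b (-0.54 ± 0.12) fell, 2 of 22, and 5 adjusted over the list alone.

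Between the combination and brivanib camera called 19 lists and fry called 6. Immune lists moved apart. Mast cell proteases Tpsb2, Cpa3, Mcpt4 and Cma1 fell by 2.24, 1.90, 2.37 and 2.24 on the log2 scale. They made up 4 of 6 markers over all genes and 4 adjusted over the list alone, with a median of -2.07 (adjusted p = 1.31e-05, adjusted p = 0.12 with an estimated correlation). Of 20 chemokines Ccl12 (-1.78 ± 0.27), Cxcl14 (-2.77 ± 0.61), Ccl11 (-1.54 ± 0.35) and the neutrophil attractant Cxcl5 (-2.62 ± 0.61) fell. Adjusted over the list alone 6 fell and 1 rose, with a median of -0.57 (adjusted p = 2.11e-05, adjusted p = 0.24 with an estimated correlation). Macrophage markers had a median of -0.86 (adjusted p = 2.72e-05, adjusted p = 0.45 with an estimated correlation). Gpnmb rose (1.43 ± 0.24), 1 of 21, and 9 fell and 2 rose adjusted over the list alone. The antigen presenting H2-Ab1 (-2.26 ± 0.47) and H2-Eb1 (-2.15 ± 0.46) fell. This was 2 of 11 MHC class II genes and 6 adjusted over the list alone, with a median of -0.66 (adjusted p = 5.12e-05, adjusted p = 0.277 with an estimated correlation). In the immunosuppressive myeloid list Chil3 rose and Retnla fell (-1.91 ± 0.47), 2 of 15. Adjusted over the list alone 5 fell and 1 rose, with a median of -0.83 (adjusted p = 0.00585, adjusted p = 0.45 with an estimated correlation), lost without brivanib 5. Single calls were lost in 23 of 27 alternatives for Retnla, in 15 of 27 for Cxcl5 and in 19 of 26 for the endothelial gene Tek. NF-kB genes had a median of -0.30 with 0 of 21 past the test over all genes and 5 lower adjusted over the list alone (adjusted p = 0.00231, adjusted p = 0.45 with an estimated correlation), lost without brivanib 2.

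Type I interferon genes had a median of 0.44 in the combination against brivanib, a call lost without brivanib 5 or combination 2 (adjusted p = 0.00241, adjusted p = 0.656 with an estimated correlation). Ifit2 rose (0.73 ± 0.14), 1 of 37, and 5 were higher and 2 lower adjusted over the list alone. Interferon-gamma genes had a median of 0.40, lost without brivanib 2 or 5 or combination 2 (adjusted p = 0.0211, adjusted p = 0.656 with an estimated correlation). The MHC regulator Nlrc5 (0.86 ± 0.20) and the peptide transporter Tap1 (0.73 ± 0.18) rose and the proteasome subunit Psmb8 fell (-0.81 ± 0.20), 3 of 27. Adjusted over the list alone 5 interferon-gamma genes rose and 1 fell. Tap1 and the DNA repair gene Brca1 lost their calls in 19 and Psmb8 in 17 of 28 alternatives. Mitochondrially encoded genes had a median of 0.69 (adjusted p = 1.09e-07, adjusted p = 0.277 with an estimated correlation). Of these mt-Nd5 (1.13 ± 0.19), mt-Nd6 (1.27 ± 0.23) and mt-Nd1 (1.02 ± 0.22) rose, 3 of 13, and 13 adjusted over the list alone. Proliferation genes had a median of 0.22, with 0 of 40 past the test over all genes and 6 adjusted over the list alone (adjusted p = 2.72e-05, adjusted p = 0.52 with an estimated correlation). DNA repair genes had 0.14, with Brca1 up (0.53 ± 0.13), 1 of 40, and 2 adjusted over the list alone (adjusted p = 0.0136, adjusted p = 0.45 with an estimated correlation), lost without brivanib 2 or combination 2 or 4. Erythroid markers fell in 5 of 5 genes over all genes and 5 adjusted over the list alone, with a median of -6.96, or -6.69 with genes at 0 set to their floor (adjusted p = 1.3e-09, adjusted p = 0.12 with an estimated correlation). Skeletal muscle, hypoxia and dendritic cell lists were called lower with medians of -1.97, -0.49 and -0.19 (adjusted p = 2.72e-05, 2.34e-06 and 0.0466, and adjusted p = 0.45, 0.45 and 0.24 with an estimated correlation). Of their 16, 32 and 14 genes 0 passed over all genes or adjusted over the list alone. The dendritic call was lost without vehicle 2, cisplatin 2, brivanib 3 or 5, or combination 2 or 4.

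The interaction asked whether brivanib acted differently in the presence of cisplatin. The genes with the smallest p were Cd209f, with -3.67 ± 0.31 (adjusted p = 0.000939), the matrix gene Fndc1 (chromosome 17, 7738569 to 7827302) with -2.82 ± 0.33, and Pi16 (chromosome 17, 29318877 to 29329413) with -3.40 ± 0.41, both at an adjusted p of 0.0129. Fndc1 stood at 0.169 ± 0.109 FPKM in vehicle, 0.492 ± 0.49 in cisplatin, 6.71 ± 0.203 in brivanib and 0.363 ± 0.25 in combination tumours (SD, n = 3). On the positive side Ifi207 (1.51 ± 0.31), Nbdy (0.63 ± 0.14) and the splicing-associated Arglu1 (0.59 ± 0.13) had the smallest p, at adjusted p of 0.0898, 0.109 and 0.109. In all 20 genes had a negative interaction past the threshold and 0 a positive one. After rescaling to equal totals these were 34 and 4. Without single libraries the count was 7 and 1 for vehicle 2 and 3, 12 for cisplatin 1, 13 for brivanib 2, 8 for brivanib 5 and 13 for combination 3. limma called 0 at a pseudocount of 0.1 (1401 at an unadjusted p under 0.05), and so did voom (1546). With the skeletal muscle score as a covariate the count was 1.

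For the interaction camera called 12 lists and fry called 2. Of the 12 that camera called, fibroblast and matrix genes had a median of -2.47 (adjusted p = 2.93e-23, adjusted p = 0.288 with an estimated correlation). Over all genes 3 of 30 passed, Pi16, Fbln1 (-3.00 ± 0.45) and tenascin Tnc (-4.52 ± 0.74), and 22 adjusted over the list alone. Tnc lost its call in 19 of 27 alternatives and Fbln1 in 15 of 26. Chemokines had a median of -1.19, with Cxcl14 at -4.55 ± 0.86 (adjusted p = 0.0711), macrophage markers -1.06 and mast cell markers -2.06 (adjusted p = 8.91e-06, 1.75e-05 and 0.00036; adjusted p = 0.288, 0.617 and 0.288 with an estimated correlation). MHC class II genes had a median of -0.98, skeletal muscle markers -2.56 and proliferation genes -0.27 (adjusted p = 7.79e-05, 1.93e-05 and 6.23e-05; adjusted p = 0.47, 0.682 and 0.732 with an estimated correlation). Endothelial, immunosuppressive myeloid, pericyte and smooth muscle, and dendritic cell lists had medians of -0.44, -0.80, -0.39 and -0.24 (adjusted p = 0.0011, 0.0294, 0.0353 and 0.0353; adjusted p = 0.732, 0.682, 0.617 and 0.288 with an estimated correlation). Cytotoxic and NK cell genes had 0.20 (adjusted p = 0.0452, adjusted p = 0.732 with an estimated correlation), a call lost in 12 of 26 alternatives. With the muscle score as a covariate the cytotoxic direction turned, to a median of -0.21, and the call ended. That covariate also ended the proliferation call and turned camera's direction for it. Over all genes 0 genes of these 11 lists passed limma's test. Adjusted over the list alone 10 chemokines, 5 MHC class II, 4 mast cell, 2 endothelial, 2 pericyte and 1 immunosuppressive myeloid gene had a negative and 1 chemokine a positive interaction. The endothelial call was lost without cisplatin 2, and the immunosuppressive, pericyte, dendritic and cytotoxic calls without several single libraries, among them vehicle 2.

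The cGAS-STING list, which the series title puts at the centre, was not called by camera or by fry's directional test in any comparison. fry's mixed test, which counts changes in either direction, passed for brivanib and the combination against vehicle and for the combination against brivanib (adjusted p = 0.0166, 0.00121 and 0.0134). The mixed test is given here for this list only, so it does not show a change particular to these genes. The list's medians over 18 genes were 0.04 for cisplatin, -0.04 for brivanib and 0.09 for the combination against vehicle (adjusted p by camera of 0.617, 0.683 and 0.469). The combination was at 0.08 against cisplatin and 0.14 against brivanib, and the interaction at 0.11 (adjusted p by camera of 0.0992, 0.18 and 0.107). The list's member Ifi204, an interferon-inducible DNA-binding protein, is named outside the rule, chosen after its values were seen. Ifi204 rose in the combination against vehicle (1.24 ± 0.25, adjusted p = 0.028) and against brivanib (1.02 ± 0.25, adjusted p = 0.0442), the 1 of 18 that passed in each. Adjusted over the list alone 3 rose and 1 fell against vehicle and 2 rose against brivanib. Cgas itself (chromosome 9, 78430526 to 78443237) lay under the expression filter, at 0.263 ± 0.0961, 0.243 ± 0.131, 0.664 ± 0.245 and 0.307 ± 0.188 FPKM in vehicle, cisplatin, brivanib and combination (SD, n = 3). With no filter its log2 fold change was 0.39 ± 0.14 for brivanib against vehicle (adjusted p = 0.307). The interferon gene Ifnb1 had 2 fragments in brivanib 3 and 2 in combination 4 and 0 in the other 10 libraries, a level at which no difference was detectable at this depth. The T cell co-receptor Cd8a, also under the filter, was at 2.35 ± 2.14 FPKM in vehicle and 0.071 ± 0.123 in combination tumours. With no filter this was a log2 fold change of -1.41 ± 0.46 (adjusted p = 0.225). Cisplatin and brivanib alone were at -1.08 ± 0.46 and -0.97 ± 0.46 against vehicle (adjusted p = 0.499 and 0.515). The combination was at -0.33 against cisplatin and -0.44 against brivanib, so the lower level is not shown to be particular to it.

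None of the 14 fixed panel genes above the filter passed the test in any of the 6 contrasts. Tmem173, which encodes STING, stood at 20.4 ± 1.97 FPKM in vehicle and 22.2 ± 2.1 in combination tumours (0.12 ± 0.12, adjusted p = 0.625). The kinase Tbk1 and the factor Irf3 were at log2 fold changes of -0.22 ± 0.10 and -0.11 ± 0.13. In the same contrast the interferon-induced Isg15 was at 0.95 ± 0.35 (adjusted p = 0.162) and the chemokines Ccl5 and Cxcl10 at 0.79 ± 0.31 and 0.04 ± 0.28. The checkpoint ligand Cd274 was at 0.71 ± 0.26 and the cytotoxic protease Gzmb at -0.47 ± 0.37. The brivanib target Kdr, the main VEGF receptor, was at 0.21 ± 0.22 for brivanib and -0.35 ± 0.22 for the combination (adjusted p = 0.771 and 0.416). Flt1 was at 0.14 ± 0.25 and -0.09 ± 0.25, Fgfr1 at -0.39 ± 0.15 and -0.20 ± 0.15, and Vegfa at 0.32 ± 0.34 and -0.25 ± 0.34. The p53 target Cdkn1a stood at 0.76 ± 0.34 for cisplatin and 1.28 ± 0.34 for the combination against vehicle (adjusted p = 0.332 and 0.0695). The proliferation marker Mki67 was at 0.44 ± 0.16 and 0.28 ± 0.16 (adjusted p = 0.238 and 0.385).

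Another 7 lists were called by camera in none of the 6 contrasts. Their smallest adjusted p by camera was 0.0636 for T cell checkpoint and exhaustion genes, 0.0827 for epithelial-mesenchymal genes, 0.0982 for platinum transport genes, 0.195 for immediate early genes, 0.368 for antioxidant and metallothionein genes, 0.389 for FGF signalling and 0.602 for apoptosis regulators. fry's directional test called a pair of them against vehicle, the epithelial-mesenchymal genes for cisplatin and the combination (adjusted p = 0.00289 and 0.0254) and the platinum transport genes likewise (adjusted p = 0.0389 and 0.0356). Some of their members passed over all genes, and a part of these is named here, chosen after their values were seen. The T cell checkpoint receptor Havcr2 rose in the combination against vehicle (1.54 ± 0.28, adjusted p = 0.0227) and against brivanib (1.49 ± 0.28, adjusted p = 0.0187). Tigit, a further checkpoint receptor (0.87 ± 0.18), and Casp8, the caspase of death receptors (0.48 ± 0.09), rose in the combination against vehicle, at adjusted p of 0.0311 and 0.0227. The drug pump Abcb1b rose by 0.52 ± 0.13 against brivanib. Against brivanib the inflammatory caspase Casp4 (0.94 ± 0.15) and the transcription factor Snai2 (0.81 ± 0.20) were also higher in the combination. The necroptosis kinase Ripk3, the factor Egr2 and the ectonucleotidase Entpd1 fell by 0.83, 0.72 and 0.62 on the log2 scale. Klf4, a transcription factor of the immediate early list, rose with brivanib against vehicle (1.26 ± 0.28, adjusted p = 0.0451).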

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

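All tests of explanations in this part were chosen after the results were seen, while the counts under other splits of the samples were planned. The interaction asks whether the effect of brivanib differed with and without cisplatin, and its results stand here because the difference itself was tested. limma called 20 genes, all with a negative interaction. The 5 named genes were the C-type lectin Cd209f (-3.67), Fndc1 (-2.82), the fibroblast gene Pi16 (-3.40), Fbln1 (-3.00) and tenascin Tnc (-4.52). Camera called 12 lists at the preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.288. Their medians were -2.47 for fibroblast and matrix genes, -1.19 for chemokines, -1.06 for macrophage markers, -2.56 for skeletal muscle markers, -0.27 for proliferation, -0.98 for MHC class II, -2.06 for mast cell markers, -0.44 for endothelial markers, -0.80 for immunosuppressive myeloid genes, -0.39 for pericyte and smooth muscle markers, -0.24 for dendritic cell markers and 0.20 for cytotoxic and NK cell genes.

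Other splits of the same samples were counted. For the interaction 100 splits were used. In 1 of them, the real one, 20 genes were called, and the highest other had 6. For the 12 lists 60 of the 100 splits did as well, the highest with 19. These splits mix samples across all 4 groups, so the effects of each drug alone enter the spread within groups and hold counts of genes low by design. They are no measure of chance without an interaction and decide neither count. The gene count was itself 0 with voom and with limma at a pseudocount of 0.1 (1546 and 1401 genes at an unadjusted p under 0.05), and 1 with the muscle covariate or without vehicle replicate 3. Each pairwise comparison has only 10 splits, too few for a share under 0.05. Every other split of a pair also mixes samples of both groups. Any real difference then enters the spread within groups and holds gene counts low by design. Low counts under other splits are therefore no support for the calls. Gene counts of the real and the highest other split were 27 and 0 for cisplatin against vehicle, 258 and 1 for brivanib, 333 and 2 for the combination, 0 and 2 for the combination against cisplatin, and 551 and 4 against brivanib, and 1, 1, 1, 10 and 1 splits reached the real count. For lists these pairs were 10 and 13, 16 and 17, 14 and 16, 7 and 14, and 19 and 22, and 5, 4, 3, 9 and 3 splits reached the real count.

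Globin transcripts were lower in cisplatin than in vehicle tumours. Scaling is argued against, since over 5 other scalings the highest median of the erythroid list was -6.57. Reads moved between near-identical globin copies are argued against by the summed globin FPKM, which fell by 6.74 on the log2 scale. Each of these copies had already been seen to fall, so the sum is no separate evidence. Alas2, a single-copy gene, was also lower and past the test. Less blood of every kind in the tumour piece stays open: 3 platelet genes had a median of 0.49, but macrophages also express Pf4 and Ppbp, so these genes do not decide it. Fewer young red cells under treatment stay open as well and were not tested.

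Matrix genes were higher in brivanib than in vehicle tumours. Carried-along tissue was weighed with scores of other lists as covariates: the matrix median was 2.39 with the skeletal muscle score and 2.09 with the adipocyte score, which argues against either tissue as the whole source. The library rich in ribosomal features is argued against by a median of 2.37 without brivanib replicate 5. Other connective tissue at the tumour's edge and a change of the tumour's own stroma stay open and were not tested. The same holds for the lower matrix and mast cell genes in the combination against brivanib, and for the interaction.

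Tsc22d3, Per1, Fkbp5, Sgk1 and Klf9, which glucocorticoids induce, were higher in the combination than in vehicle tumours, with log2 fold changes of 2.42 ± 0.46, 1.47 ± 0.28, 1.29 ± 0.23, 1.25 ± 0.22 and 1.15 ± 0.25 (SE). With cisplatin alone they were at 1.31, 1.30, 1.0, 0.91 and 0.86 without passing the test (adjusted p from 0.0827 to 0.219), and with brivanib at -0.07, -0.37, -0.09, 0.02 and -0.20, so the rise is not shown to be particular to the combination. Without combination replicate 3 they were 1.90 ± 0.41, 1.39 ± 0.32, 1.07 ± 0.23, 1.02 ± 0.20 and 0.92 ± 0.25, so that library is not the whole source of these folds. An unadjusted p under 0.05, held by 5 of 5, adds little, since the genes were noticed for passing in these same data. The adjusted calls ended, at 0.0683 to 0.121, with 1 sample fewer. A wider rise of glucocorticoid-responsive genes stays open: the other 14 had a median of 0.41 (adjusted p = 0.00929, adjusted p = 0.311 with an estimated correlation). Stress of the animals may be a source, as may an effect of the drugs, and neither was tested.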

How the results depend on the processing

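Rescaling without ribosomal-like features, voom and both covariates were chosen after the data were seen, and the other alternatives were planned. Values are counts called by limma (genes) or camera (lists) that moved by over 1.5 times, and the cause was not tested unless stated. With a pseudocount of 0.1 there were 13 genes for cisplatin against vehicle and 0 for the interaction (1401 at an unadjusted p under 0.05), and with 5 there were 52 for the interaction. With no filter there were 7 for cisplatin, 125 for the combination against vehicle and 3 against cisplatin. With a mean FPKM of at least 5, which tests fewer genes, there were 45 for cisplatin, 69 for brivanib, 317 for the combination against brivanib and 2 for the interaction, and 6 lists for cisplatin and 4 for the combination against cisplatin. Rescaling to equal totals gave 13, 160 and 85 genes for cisplatin, brivanib and the combination against vehicle, 1 against cisplatin, 269 against brivanib and 38 for the interaction, and 17 lists for cisplatin and 13 for the combination against cisplatin. For cisplatin, median-of-ratios scaling gave 14 genes and quantile normalization 16. A fit of only the groups compared gave 42 for cisplatin and 138 for the combination against brivanib. Sample weights gave 335, 452 and 912 against vehicle, 1077 for the combination against brivanib and 35 for the interaction. With transcripts as features there were 7, 101 and 52 against vehicle, 15 for the combination against cisplatin and 74 against brivanib. An estimated correlation left 0 lists in all 6 contrasts. Without ribosomal-like features there were 11 genes for cisplatin and 7 for the interaction. voom gave 0 genes for cisplatin (1855 unadjusted), 0 for the interaction (1546) and 3 lists for the combination against cisplatin. The muscle covariate gave 62 genes for brivanib, 1 for the interaction and 6 lists for cisplatin. The adipocyte covariate gave 1, 24 and 0 genes against vehicle (1462 unadjusted for the last) and 15 lists for the combination against cisplatin. Under each covariate its own list was left out.

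No pairing by replicate number was seen: deviations from the group mean had a median correlation of -0.013 over 13 pairs with the same number and 0.02 over 41 other pairs. These ranged from -0.157 to 0.213 and from -0.232 to 0.231, so a modest pairing is not excluded. With the number as a replicate block there were 0 genes for cisplatin (1455 unadjusted), 35 for the combination against vehicle, 168 against brivanib, of which 30.4% were higher, and 1 for the interaction.

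Leaving out each library in turn gave 0 to 100 genes for cisplatin against vehicle, 116 to 282 for brivanib, 21 to 525 for the combination, 0 to 2 against cisplatin, 61 to 646 against brivanib and 1 to 27 for the interaction. Lists ranged from 7 to 16, 15 to 19, 9 to 16, 5 to 10, 15 to 22 and 8 to 19. Of 78 called lists 50 kept their call without any 1 library and 28 lost it without some library. Over 26 or 27 alternatives, the estimated correlation aside, calls were lost most often for endothelial markers with cisplatin (15), dendritic cell markers in the combination against brivanib (13), cytotoxic and NK cell genes in the interaction (12), hypoxia genes in the combination against vehicle (11) and erythroid markers against cisplatin (11). For brivanib against vehicle the muscle covariate ended the calls of type I interferon, dendritic cell, erythroid and adipocyte lists, and the adipocyte covariate those of type I interferon, dendritic cell and proliferation lists. A group left with 2 samples is assumed to vary like the others.

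A few directions turned, by the sign of a gene or of camera for a list. Hypoxia response, brivanib against vehicle, had a median of -0.039 without brivanib replicate 2 and 0.635 without brivanib replicate 3, and Xpo7 and Cd82 had 0.71 and 0.09 with transcripts as features. With the muscle covariate, cytotoxic and NK cell genes had 0.26 for brivanib and -0.21 for the interaction, and proliferation genes 0.025 and -0.029. With the adipocyte covariate, cytotoxic and NK cell genes had 0.15 for brivanib and hypoxia genes 0.35 for the combination against vehicle. Over all named genes and settings 10258 values stayed called or shifted by at most 1 SE while not called, 619 that were not called shifted by more, 1142 lost and 258 gained a call, and 2 turned. For lists 5182 stayed on the same side of the threshold, 244 lost and 215 gained a call, and 7 turned.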

Other observations

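The lists in this part were chosen after the data were seen, from groups of genes noticed among the changes, so they describe these data only. Cholesterol synthesis genes were lower with both drugs: 0 of 22 had a positive log2 fold change in the combination against vehicle, with a median of -0.80 (adjusted p = 2.36e-11, adjusted p = 0.136 with an estimated correlation), and 3 fell over all genes. Sqle, an enzyme of the sterol pathway, fell from 31.9 ± 7.3 to 13.6 ± 2.19 FPKM (SD, n = 3), or by 1.16 on the log2 scale (adjusted p = 0.0235), Msmo1 by 1.06 and the sterol sensor partner Insig1 by 0.93. The same list had a median of -0.63 against brivanib, where 1 gene fell (adjusted p = 5.85e-10, adjusted p = 0.208 with an estimated correlation). Against cisplatin the median was -0.45 (adjusted p = 1.34e-07, adjusted p = 0.175 with an estimated correlation). Cisplatin alone against vehicle went the same way, at -0.24 (adjusted p = 0.000274, adjusted p = 0.772 with an estimated correlation), and brivanib alone was at -0.01 (adjusted p = 0.746). A list of fatty acid oxidation genes and PPAR targets was higher in the combination than in vehicle tumours, with a median of 0.52 (adjusted p = 8e-05, adjusted p = 0.136 with an estimated correlation). Of its 18 genes 15 had a positive log2 fold change and 5 passed the test. These were Cd36, Angptl4, Acot2, Cpt1a (1.26 ± 0.22) and the carnitine carrier Slc25a20 (0.78 ± 0.15). The oxidation enzymes did not rise as a whole. Acadl, Acaa2 and Ech1 were at 0.60, 0.49 and 0.47 without passing. Hadhb, Acadvl, Cpt2, Acadm, Hadha and Eci1 were at 0.105, 0.04, 0.02, -0.09, -0.12 and -0.41. Adipocyte markers moved with the list, at 3.22 to 3.579 in combination and 1.545 to 1.609 in vehicle libraries, and Cd36 is in both lists. With the adipocyte score as a covariate limma called 0 genes in this contrast (1462 at an unadjusted p under 0.05). Lost calls do not show that the folds ended. Cd36 and Angptl4 kept log2 fold changes of at least 1.388 and 1.399 over 28 alternatives, this covariate among them. Fat cells in the tumour pieces stay open as a source.

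Complement and acute phase genes were higher with brivanib than with vehicle, with a median of 1.80 and 10 of 19 up (adjusted p = 6.17e-14, adjusted p = 0.0245 with an estimated correlation). They include Lbp, which binds bacterial lipopolysaccharide (2.86 ± 0.27, adjusted p = 0.000555), and the complement genes C3 (3.71 ± 0.48), Cfb (3.17 ± 0.39), C4b (3.06 ± 0.53) and Serping1 (3.75 ± 0.54). The list's interaction median was -0.93, with 1 gene past the test (adjusted p = 1.51e-05, adjusted p = 0.252 with an estimated correlation). In the combination against vehicle the median was 0.83, with 4 up (adjusted p = 3.71e-05, adjusted p = 0.136 with an estimated correlation). Adipocyte and matrix scores moved with brivanib too, at 2.195 to 4.34 and 5.757 to 6.12. In vehicle they were at 1.545 to 1.609 and 3.374 to 4.356, and carried-along tissue was not tested as a source here. Mitochondrial transfer RNAs, whose levels are uncertain because they are shorter than usual fragments, had a median of 1.46 in the combination against brivanib with 9 of 22 up (adjusted p = 1.47e-10, adjusted p = 0.135 with an estimated correlation). The median was -0.41 for brivanib against vehicle (adjusted p = 0.00181, adjusted p = 0.558 with an estimated correlation), and brivanib 5, the library rich in ribosomal features, stood low. There mt-Te, mt-Tp and mt-Th had 12.4, 6.39 and 4.97 FPKM, against 44.9, 41.4 and 31.1 in brivanib 2 and 86.9, 38.7 and 51.4 in brivanib 3. The list had a median of 0.67 for cisplatin against vehicle with 1 up (adjusted p = 8.3e-06, adjusted p = 0.456 with an estimated correlation).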
